A study of Mus musculus with 6 samples.

How the data were processed

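Gene expression was measured by RNA sequencing of liver from male C57BL/6 mice reared for 71 weeks, in 3 libraries from mice on normal chow (called control here) and 3 from mice on chow with polystyrene microplastic (PS-MP). Per the labels, total RNA was purified with a column kit, polyadenylated RNA was selected, and directional libraries were made. The submitters' processing notes name bcl2fastq and the genome build GRCm39. The aligner, the counting program, the annotation release, the strand setting, the particle size and the dose are not given in the sources used here. The deposited files hold, per the labels and by their values, unnormalised whole-number read counts per gene, with ribosomal and mitochondrial RNA included. A deposited table of the whole series holds the same counts as the 6 files of single libraries, which were used here.

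Each file lists 56674 genes under 55802 distinct symbols; the counts of the 67 symbols listed more than once were summed. A reference annotation of an earlier genome build holds 90.8% of the symbols, so it was used only to find the genes next to a named gene, and no coordinates are given. Because the strand setting is not given, reads from overlapping genes on opposite strands cannot be told apart. Genes with near-identical copies, such as members of the Cyp2c, Cyp3a, Cyp4a, Gstm, Mup and globin families, share reads, and the values of single members are uncertain.

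Counts were analysed with R 4.3.3. Genes of low count were removed by the filter of edgeR 4.0.16 (filterByExpr by diet), which left 17662 genes. Counts were scaled by trimmed mean of M values (TMM), and diets were compared with the quasi-likelihood F test of edgeR, with diet as the one term and p adjusted by Benjamini and Hochberg over all genes tested. Log2 fold changes are PS-MP minus control. The 95% confidence interval of each comes from its standard error (SE) and the moderated degrees of freedom, 6.63. Levels are TMM-scaled CPM, counts scaled to a common library total, as mean and standard deviation (SD) of 3 libraries. Single measures were compared by two-sided exact permutation tests over the 10 splits of 6 libraries into 3 and 3, whose smallest possible p is 0.1. Intervals and floors on low counts cover counting error only.

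The tests, the alternatives, the rule for naming genes and 58 gene lists were fixed before the data were examined. The lists cover metabolism, the response to foreign compounds, stress, inflammation, growth, sex-biased and zonated liver genes, the circadian clock, and markers of the cell types that a piece of liver could hold. The 56 lists with at least 5 measured genes were tested with camera of limma 3.58.1, two-sided, on log2 CPM with a prior count of 2. Camera compares the genes of a list with all other genes. It was run with a preset correlation of 0.01 between genes, with p adjusted over the 56 lists, and again with a correlation estimated for each list. The rotation test fry asked whether the genes of a list move one way, without comparing them with other genes. Member genes were also tested with p adjusted over the list alone. For the genes of the 15 metabolism lists, those whose 95% interval lay inside 2-fold, that is between -1 and 1 on the log2 scale, were counted.

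Named genes were the 5 with the smallest p in each direction, whether past the threshold or not where fewer than 5 passed, leaving out predicted genes, pseudogenes and unnamed loci. To these were added the 3 members with the smallest p in the direction of each list past the threshold, members past the threshold over their list alone, and 24 genes fixed whatever their values. Not every gene that this rule gives is printed. Any other gene named was chosen after its values were seen.

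Alternatives were other scalings (DESeq2-type size factors, upper quartile, library size only), no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersions, other thresholds, removal of mitochondrially encoded genes, the replicate number as a block, and leaving out each library in turn. With a library left out the filter was run anew and 18172 to 18467 genes were tested, so list means there can rest on other members. Ranks, other distances and another prior count were also tried. Added after the data were seen were a clock index as a covariate, removal of ribosomal RNA genes, and removal of genes whose CPM spanned over 16-fold within a diet. The edgeR fit and the list test were tested on simulated counts of the same depth and spread. With 17214 genes, 61 of 100 genes changed 4-fold and 5 of 100 changed 2-fold were called, with 8 unchanged genes called. There, 95.3% of the intervals held the true value, and with no change simulated (17231 genes) 0 genes and 0 lists were called. Simulated genes were drawn independently, so the 0 lists do not show how the list test behaves with correlated genes. In the real libraries, the splits other than that by diet gave 4 to 23 lists with the preset correlation.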

Results

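The data are 6 liver transcriptomes, 3 from male mice on control chow and 3 from males on chow with PS-MP, plastic particles of polystyrene. The labels describe mice reared over 71 weeks, and the series asks how prolonged exposure affects gene expression in the liver. Its title speaks of no effect on metabolism. Control libraries held 75897165, 68357478 and 112566641 counts, and PS-MP libraries held 79081889, 79317092 and 79691824. The largest total was 1.65-fold the smallest. The labels do not state that replicates are separate animals, so the p-values measure the spread between these samples.

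Libraries of one diet were slightly more alike than libraries of different diets. Across the 17662 genes tested, the log2 CPM of libraries of one diet correlated with a mean r of 0.957 (range 0.947 to 0.962, 6 pairs), and those of different diets with a mean r of 0.953 (range 0.943 to 0.959, 9 pairs). Pairs of PS-MP libraries lay between 0.958 and 0.961, and pairs of control libraries between 0.947 and 0.962. These correlations are across genes, which are not independent replicates. The mean distance between diets was 1.09 times that within diets. This ratio was the highest of the 10 splits of the libraries, where the others reached 1.08 (exact permutation p = 0.1, the smallest possible). Without PS-MP replicate 2 the ratio was 1.03, without PS-MP replicate 1 it was 1.04, and without PS-MP replicate 3 it was 1.09 (exact p = 0.4, 0.3 and 0.2).

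Ribosomal RNA and the number of genes detected did not overlap between the diets. Reads of 18S ribosomal RNA (Rn18s-rs5), which poly(A) selection should remove, took 2.92%, 11.2% and 1.15% of the counts in control and 1.14%, 0.599% and 0.387% in PS-MP (two-sided exact permutation p = 0.1, n = 3 and 3). Genes with at least 1 count numbered 23042, 23791 and 23625 in control and 24004, 24557 and 24763 in PS-MP (exact permutation p = 0.1). Alb, the gene of serum albumin, took 5.40%, 4.18% and 4.80% of the counts in control and 6.72%, 5.34% and 6.28% in PS-MP, which overlap (exact permutation p = 0.2).

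Among single genes, 2 rose with PS-MP and 0 fell. Dennd5b, whose product belongs to a family of regulators of Rab proteins in membrane traffic, was low but measured in every control library, with 66, 125 and 96 counts or 1.29 ± 0.661 CPM (SD, n = 3). It stood at 79.0 ± 17.6 CPM in PS-MP (SD, n = 3), which is 61.8-fold higher (95% interval 30.1 to 127; log2 fold change 5.95, SE 0.43, edgeR adjusted p = 0.0365). The other, Gm5526, is a processed pseudogene and was chosen after its values were seen, since the naming rule passes over pseudogenes. It had 1 count in each control library and 186, 192 and 212 counts in the PS-MP libraries, a ratio of 184 (counting interval 62.5 to 893, adjusted p = 0.00353). Both genes were higher in 3 of 3 PS-MP libraries than in any control library, and 4 of the 10 splits of the libraries, that by diet among them, held some gene with its low and high libraries as far apart as those of Gm5526. Reads of a processed pseudogene can come from its parent gene, so the source of the Gm5526 counts is uncertain. At an unadjusted p under 0.05, edgeR had 494 rising and 456 falling genes, where 883.1 in all would be expected with no change. Scaling by library size alone gave 1461 rising and 224 falling. DESeq2 called 187 genes, 62 rising and 125 falling with Dennd5b and Gm5526 among them, and limma-voom called 1, Dennd5b, with 0 falling. Dennd5b kept its call when control replicate 2 was left out, but its adjusted p rose to 0.182 without control replicate 1, 0.302 without control replicate 3, 0.0883 without PS-MP replicate 1, 0.144 without PS-MP replicate 2, 0.0965 without PS-MP replicate 3 and 0.299 with the clock index described with the clock genes. With a library left out its log2 fold change stayed between 5.75 and 6.44. Gm5526 lost its call without control replicate 3 (adjusted p = 0.0689) and with limma-voom (adjusted p = 0.0721), where its log2 fold change was 7.26 and 6.90, against 7.51 with all libraries in edgeR. The number of genes called was 4 without control replicate 2, 0 without control replicate 3, and 1 without PS-MP replicate 1 or 3.

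**Figure D1:**
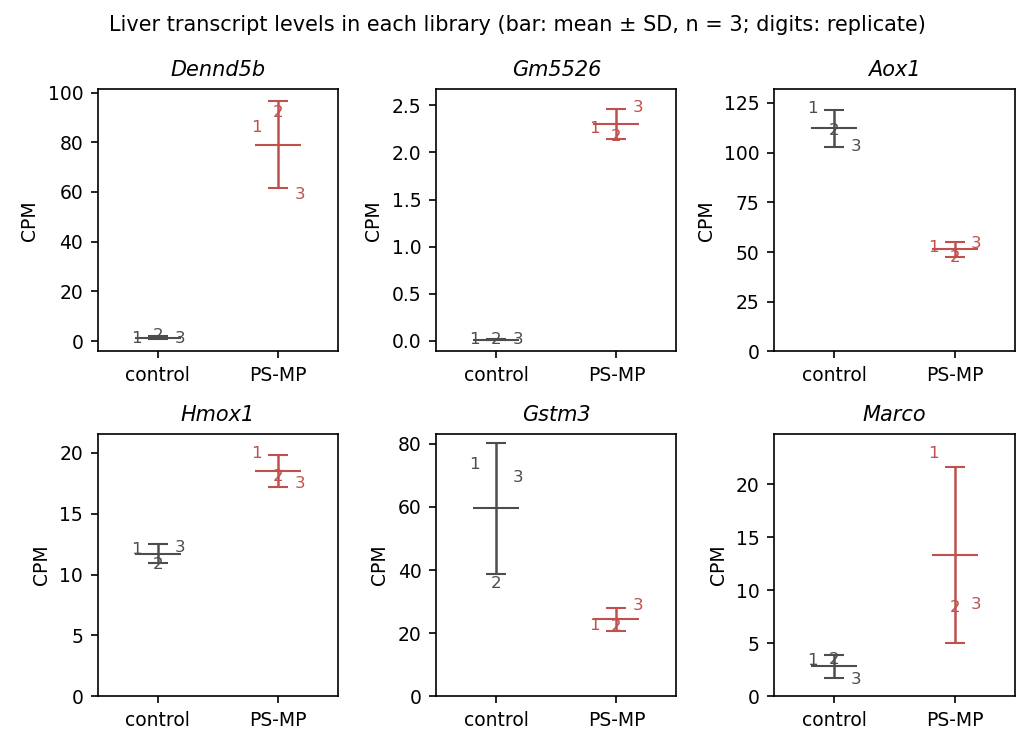
TMM-scaled CPM (linear axis) of 6 genes in each library, with the replicate number at each point and bars for the mean ± SD of 3 libraries per diet. Dennd5b averaged 1.29 CPM in control and 79.0 CPM in PS-MP, while Aox1, Hmox1, Gstm3 and Marco did not pass the test over all genes.

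The named genes with the next smallest p did not pass over all genes. Dock9, an activator of the small GTPase Cdc42, had a log2 fold change of 4.50 (SE 0.45, adjusted p = 0.143) from a control level of 0.336 CPM. Kyat3, an aminotransferase of the kynurenine pathway, had 2.40 (SE 0.33, adjusted p = 0.473). Trip12, a ubiquitin ligase, had 1.17 (adjusted p = 0.512) and Gmppa, which takes part in the control of GDP-mannose, had 1.12 (adjusted p = 0.473). On the lower side, Aox1, an aldehyde oxidase that oxidises many foreign compounds, averaged 112 ± 9.53 CPM in control and 51.3 ± 3.70 in PS-MP (SD, n = 3; log2 fold change -1.13, SE 0.12, adjusted p = 0.193). Neurl4 had -1.94 (adjusted p = 0.512) and Atxn2l -1.46 (adjusted p = 0.767). Retn, the gene of the adipocyte hormone resistin, had 64 counts over the control libraries and 0 over the PS-MP libraries, at least 22.8-fold lower by a floor of 3 counts over the group (adjusted p = 0.767). DESeq2 called these 8 genes. The libraries of the diets did not overlap for 1984 genes (1102 higher and 882 lower in PS-MP), which is 11.2% of the genes tested where chance gives 10%.

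Metabolic genes were compared by the size of change that these libraries exclude. Of the 320 genes on the 15 metabolism lists, 310 were tested, and the 95% interval of 191 (61.6%) lay inside a 2-fold change. The same held for 53.5% of all genes tested, and the other splits of the libraries gave 185 to 208 such metabolic genes. With edgeR, 0 of the 310 passed over all genes; 33 had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 3 (Creb3l3 and Slc39a14 lower, Hmox1 higher). Intervals lay below zero for 24 genes and above zero for 9. Cpt1a, the gate of fatty acid entry into mitochondria, had a log2 fold change of -0.14 (interval -0.49 to 0.20). Pck1, of gluconeogenesis, had -0.03 (-0.74 to 0.68), the fatty acid transporter gene Cd36 0.06 (-0.56 to 0.68), Pparg -0.11 (-0.71 to 0.49) and Igf1 0.07 (-0.51 to 0.65), so changes of 2-fold lay outside their intervals. For other genes a 2-fold change was not excluded at this spread. These included Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis (-0.02, with an interval that starts at -1.03), the hormone gene Fgf21 (0.11, -1.61 to 1.82) and the fatty acid synthase gene Fasn (-0.65, -1.53 to 0.23). Creb3l3, a transcription factor of hepatic lipid metabolism, was the only metabolic gene whose whole interval lay below -1 (log2 fold change -4.42, -6.96 to -1.88, adjusted p = 0.767). Its levels were 289, 12.4 and 293 CPM in control and 9.07, 8.82 and 9.90 CPM in PS-MP, and without control replicate 2 it passed (adjusted p = 0.00102). It also passed with DESeq2 (adjusted p = 9.4e-05), while with any other single library left out its adjusted p was at least 0.664.

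As groups, 8 of the 15 metabolism lists were lower in PS-MP than other genes were. Of all 56 lists tested, 21 passed with the preset correlation, 5 higher and 16 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.553; 0 lists at an unadjusted p under 0.05), and fry passed 0 (smallest adjusted p = 0.159; 4 at an unadjusted p under 0.05). Over all genes, 0 of the 960 genes on the lists passed with edgeR (78 at an unadjusted p under 0.05), 0 with limma-voom and 12 with DESeq2. The 21 lists hold 387 distinct genes, 27 of them on more than 1 list. Scaling by library size alone moved the log2 fold changes of all genes up by a median of 0.212. Camera compares a list with the other genes, but the list medians and means given here move with the scaling. The mean of bile acid synthesis, -0.272, was -0.0598 with library size alone. The libraries these lists compare differed in Rn18s-rs5 too, at 5.08% ± 5.36 of counts in control and 0.709% ± 0.389 in PS-MP (SD, n = 3). The mean levels of the libraries did not overlap between diets for 8 of the 56 lists tested (14.3%, where chance gives 10%); among the 21 that passed they overlapped for 15.

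Fatty acid synthesis fell as a group, with 17 of 22 genes below zero, a median log2 fold change of -0.53 and adjusted p = 0.000214. It did not pass with an estimated correlation (adjusted p = 0.553 with an estimated correlation). Scd1, the main hepatic stearoyl-CoA desaturase, averaged 5657 ± 2010 CPM in control and 2460 ± 764 in PS-MP (SD, n = 3), with a log2 fold change of -1.20 (SE 0.35, interval -2.03 to -0.37, adjusted p = 0.805). Elovl5, a fatty acid elongase, had -0.93 (SE 0.29) and Me1, the malic enzyme that supplies NADPH, -1.28 (SE 0.41). No member passed when adjusted over the list alone. Acaca, which makes malonyl-CoA and was singled out after its values were seen, had 3, 15 and 1263 counts in control and 2300, 376 and 1285 in PS-MP. The mean log2 CPM of the list overlapped between diets, at 5.62 to 6.16 in control and 5.62 to 5.90 in PS-MP (exact permutation p = 0.4). Control replicate 2 was the lowest control for this list and for adipocyte markers, whose mean log2 CPM was 1.37 there, 1.92 in control replicate 1, higher still in control replicate 3, and 1.13, 0.97 and 1.37 in PS-MP. On average the list had a log2 fold change of -0.370, but -0.196 without control replicate 1 and -0.149 without control replicate 3. Leaving out control replicate 3 left Acaca with 3 and 15 control counts, so the value of -0.149 rests in part on Acaca. Without genes of wide spread, Acaca among them, the list mean was -0.481.

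**Figure D2:**
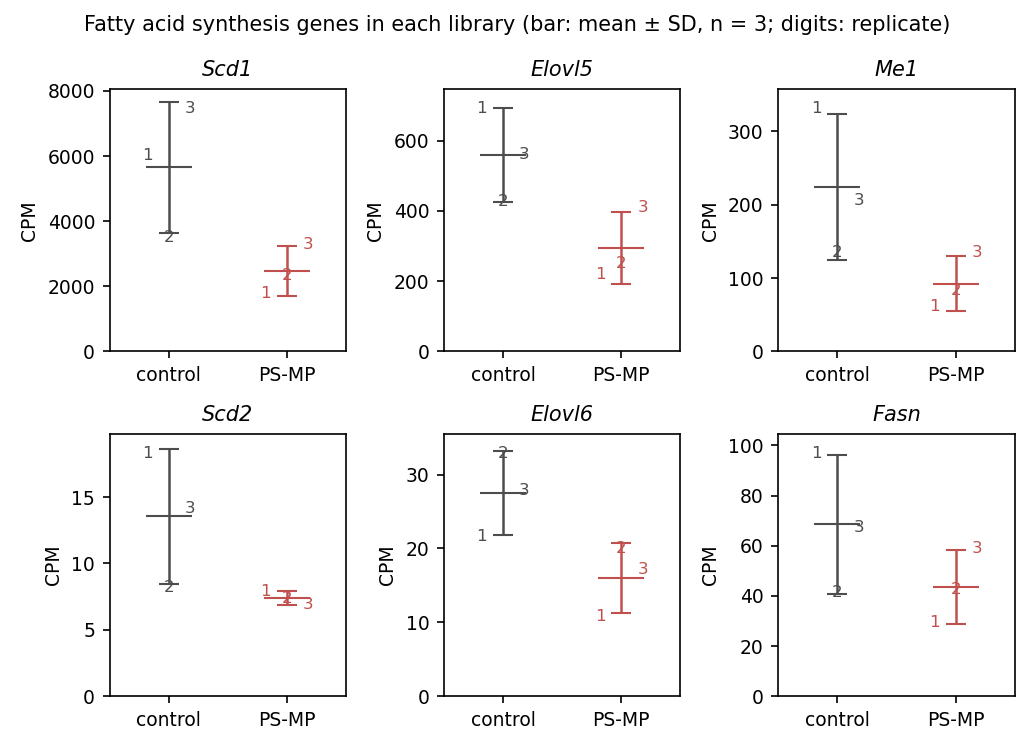
TMM-scaled CPM of 6 genes of fatty acid synthesis in each library (digits, the replicate numbers; bars, mean ± SD of 3 libraries per diet). Scd1 averaged 5657 CPM in control and 2460 CPM in PS-MP; Scd2 and Elovl6 were added after their values were seen, and no gene passed the test over all genes.

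Lists of fat storage and burning were also lower. The lipid droplet list had 18 of 23 genes below zero, a median of -0.23 and adjusted p = 0.000701 (adjusted p = 0.581 with an estimated correlation). Its members with the smallest p were Fitm2, which helps form droplets (-0.97), the monoglyceride lipase gene Mgll (-0.66) and Apoa4 (-1.09). The mean log2 CPM of the list was 5.70, 5.13 and 5.71 in control and 4.87, 5.05 and 5.26 in PS-MP (exact permutation p = 0.2). Adipocyte markers, with which the list shares Cidea, were lower in each PS-MP library than in any control library (exact permutation p = 0.1). That margin was very small, with 1.369 in control replicate 2 and 1.367 in PS-MP replicate 3. The adipocyte list also holds Pck1, a gene of gluconeogenesis at 2073 CPM in control and 2029 CPM in PS-MP, so its level does not measure adipocytes alone. Fatty acid oxidation and PPARA targets had 26 of 29 genes below zero, a median of -0.16 and adjusted p = 0.000319 (adjusted p = 0.662 with an estimated correlation). Fabp1, the liver fatty acid binding protein gene, averaged 3544 ± 71.4 CPM in control and 2611 ± 612 in PS-MP (SD, n = 3; log2 fold change -0.44), and Vnn1 had -0.51. Oxidation genes, Creb3l3 among them, averaged -0.355, with -0.564 without PS-MP replicate 3 and -0.210 without genes of wide spread.

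Bile acid synthesis was lower in all 14 genes measured (median -0.34, adjusted p = 0.00162; adjusted p = 0.553 with an estimated correlation). Amacr had -0.36, Hsd17b4 -0.39 and Cyp27a1, which starts the alternative route, -0.38. These genes averaged -0.272, and -0.432 without PS-MP replicate 3. Bile acid transport had 11 of 13 genes below zero (median -0.40, adjusted p = 0.0456; adjusted p = 0.553 with an estimated correlation), with -0.91 for the uptake carrier gene Slco1b2, -0.67 for the bile salt export pump gene Abcb11 and -0.64 for Abcc4. That call held in 1 of 6 fits that left out a library, the one without PS-MP replicate 2, where the mean moved from -0.294 to -0.442. Without control replicate 1, 2 or 3, or PS-MP replicate 1 or 3, it ended (adjusted p up to 0.227; mean -0.114 without control replicate 2 and -0.183 without PS-MP replicate 1). It also ended with the 1 CPM filter (adjusted p = 0.138).

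Glycolysis, fructose and glycogen genes had 17 of 23 below zero (median -0.20, adjusted p = 0.0337; adjusted p = 0.662 with an estimated correlation; mean above zero, 0.0114, with library size alone). Examples were Pfkfb3 (-0.54), the glycogen phosphorylase gene Pygl (-0.47) and the ketohexokinase gene Khk (-0.41). The nuclear genes of the respiratory chain had 26 of 31 below zero by a small margin (median -0.09, adjusted p = 0.0337; adjusted p = 0.845 with an estimated correlation; mean above zero, 0.107, with library size alone). Cox5a had -0.43, Ndufa5 -0.20 and Ndufa1 -0.17. Both calls ended without control replicate 1 or 3 or PS-MP replicate 1 or 2 (adjusted p up to 0.408 for glycolysis and 0.354 for the respiratory chain), with the 1 CPM filter (adjusted p = 0.0675 and 0.0713) and with the clock index (adjusted p = 0.121 and 0.0711). With library size alone the call for the respiratory chain ended (adjusted p = 0.418), while that for glycolysis held (adjusted p = 0.0410). Glycolysis genes averaged -0.197, which was -0.0862 without control replicate 1, -0.130 without PS-MP replicate 2 and -0.457 without PS-MP replicate 3. Respiratory chain genes averaged -0.104, which was -0.0684 without control replicate 1, -0.169 without control replicate 2, -0.0650 without control replicate 3, -0.0569 without PS-MP replicate 1 and -0.162 without PS-MP replicate 3.

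All 13 protein genes of the mitochondrial genome were below zero (median -0.32, adjusted p = 0.000111; adjusted p = 0.553 with an estimated correlation), with mt-Atp6 at -0.35, mt-Co1 at -0.41 and mt-Nd3 at -0.52. Their mean log2 CPM lay between 12.32 and 12.66 in control and between 11.49 and 12.01 in PS-MP (exact permutation p = 0.1). As a share of all counts they took 14.6% ± 0.446 in control and 13.5% ± 1.56 in PS-MP (SD, n = 3 each; exact permutation p = 0.3). Nuclear pseudogene copies of these genes held a further 4.24% and 3.92%, so the level of single mitochondrial genes is uncertain. mt-Nd4, singled out after its values were seen, ranged from 17 to 67595 counts per library and had a log2 fold change of -2.88, where the other 12 genes lay between -0.52 and -0.13. Without mt-Nd4 the mean log2 CPM was 12.63 to 12.88 in control and 12.26 to 12.63 in PS-MP, with the ranges almost touching (exact permutation p = 0.1). The mean log2 fold change of the list was -0.498, and -0.301 without genes of wide spread.

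Genes that handle foreign compounds were lower as groups. Cytochrome P450 genes had 21 of 27 below zero (median -0.28, adjusted p = 0.000214; adjusted p = 0.553 with an estimated correlation), with Cyp3a25 at -1.21, Cyp2c55 at -0.79 and Cyp3a41a at -1.27. Targets of the receptors CAR and PXR had 15 of 18 below zero (median -0.32, adjusted p = 0.000354; adjusted p = 0.553 with an estimated correlation), among them Aldh1a7 at -0.41. Conjugation enzymes had 21 of 27 below zero (median -0.24, adjusted p = 0.00265; adjusted p = 0.553 with an estimated correlation), with Gstm4 at -0.64. This call ended without control replicate 3 (adjusted p = 0.0748). NRF2 targets had 16 of 20 below zero (median -0.31, adjusted p = 0.000499; adjusted p = 0.553 with an estimated correlation), with Cbr3 at -0.83 and the epoxide hydrolase gene Ephx1 at -0.44. Gstm3, a glutathione transferase gene on 3 of these lists, averaged 59.5 ± 20.7 CPM in control and 24.4 ± 3.70 in PS-MP (SD, n = 3; log2 fold change -1.29, SE 0.29), and was past the threshold when adjusted over the list alone for NRF2 targets. Hmox1, the haem oxygenase gene, lay the other way at 11.7 ± 0.785 CPM in control and 18.5 ± 1.31 in PS-MP (SD, n = 3; log2 fold change 0.66, SE 0.14) and passed when adjusted over the list alone both there and for iron and haem metabolism, against adjusted p = 0.767 over all genes. Of the fixed genes, Cyp3a11 had -0.51 (interval -1.09 to 0.06), Cyp2b10 -1.21 (-2.72 to 0.29), Cyp1a1 -0.44 (-1.11 to 0.22) and Nqo1 -0.11 (-0.90 to 0.68). P450 genes averaged -0.348 but -0.162 without control replicate 3, and NRF2 targets averaged -0.289 but -0.443 without control replicate 2 and -0.448 without PS-MP replicate 3. The mean log2 CPM of the P450 list was 6.61, 6.14 and 6.84 in control and 6.24, 6.20 and 6.15 in PS-MP (exact permutation p = 0.4). Control replicate 2 thus lay below every PS-MP library. Conjugation enzymes overlapped too (exact permutation p = 0.2), while CAR and PXR targets and NRF2 targets did not (exact permutation p = 0.1 for both).

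Male-biased liver genes gave the smallest p of all lists with the preset correlation, though not with an estimated correlation or fry. Of these genes 20 of 23 were below zero (median -0.45, camera adjusted p = 7.2e-06, and 0.553 with an estimated correlation). Cyp2u1 averaged 32.2 ± 0.965 CPM in control and 21.9 ± 1.37 in PS-MP (SD, n = 3; log2 fold change -0.55), and Cyp4a12b had -0.71 (SE 0.16). These 2 genes fell when adjusted over the list alone, and Cyp4a12a had -0.99. The male-biased mean, -0.562, was -0.346 without control replicate 2, -0.367 without PS-MP replicate 1 and -1.15 without PS-MP replicate 3. The mean log2 CPM of the list was 7.48, 7.84 and 7.32 in control and 6.11, 6.67 and 7.54 in PS-MP (exact permutation p = 0.3). PS-MP replicate 3 thus stood above control replicates 1 and 3. Pericentral hepatocyte genes, those expressed around the central vein, had 20 of 22 below zero (median -0.26, adjusted p = 0.000311; adjusted p = 0.553 with an estimated correlation). Glul, the glutamine synthetase gene, had -0.59, Cyp2c50 -0.32 and Rhbg -0.78. The pericentral mean, -0.294, was -0.175 without control replicate 3 and -0.633 without PS-MP replicate 3. Periportal hepatocyte genes had a median of 0.15 and did not pass (adjusted p = 0.377), nor did female-biased genes (median -0.03, adjusted p = 0.754).

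**Figure D3:**
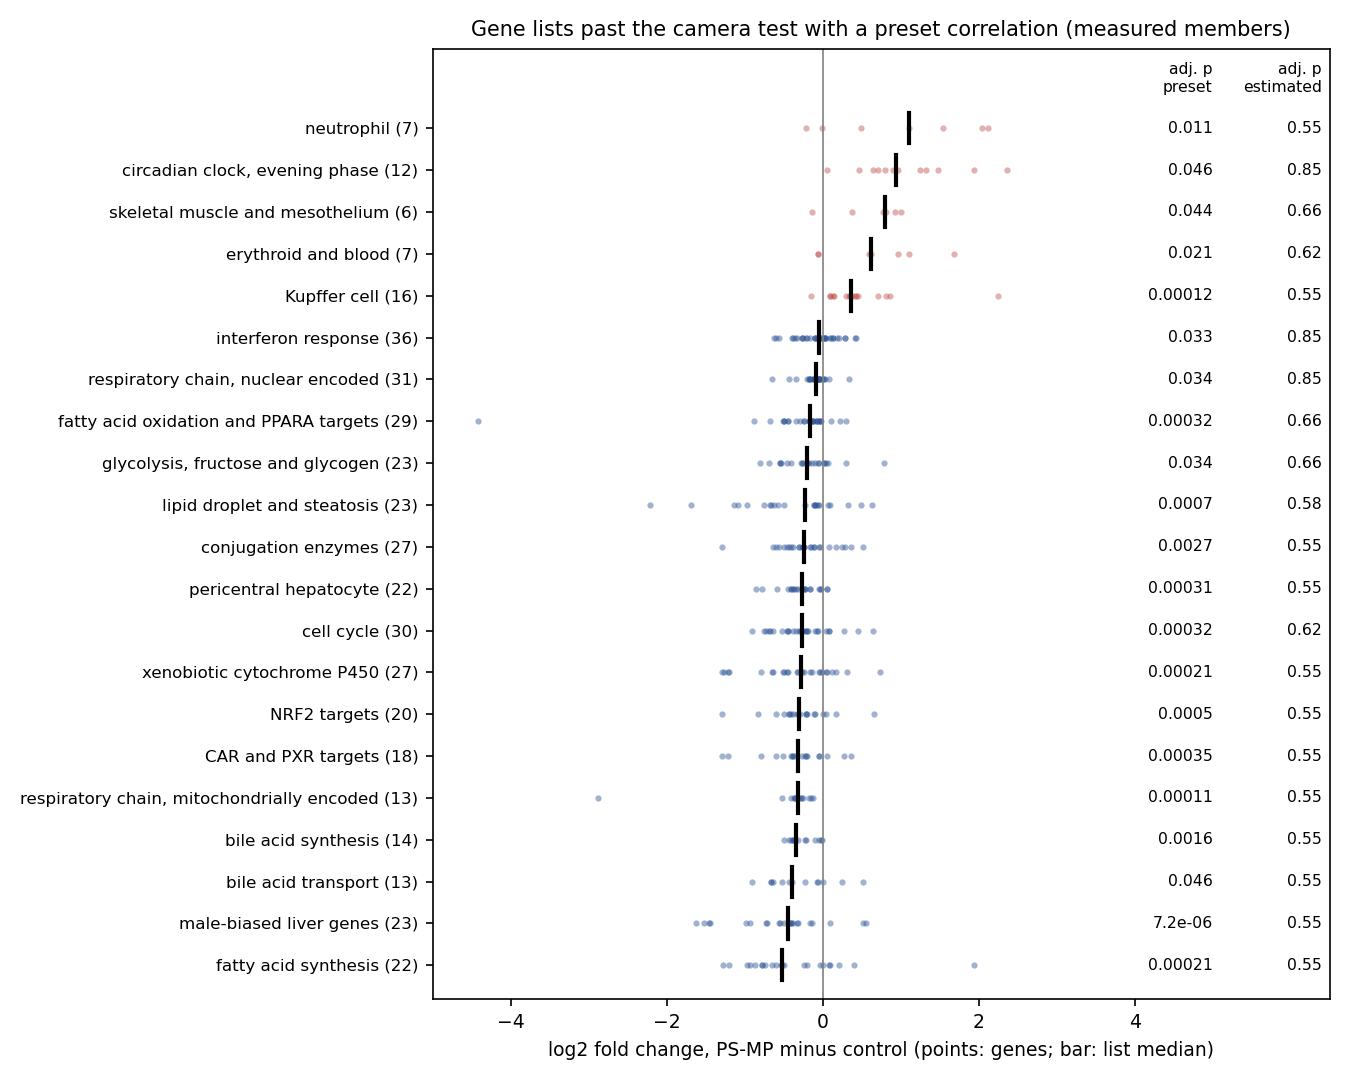
Log2 fold change (PS-MP minus control) of each measured gene on the 21 lists past the threshold with the preset correlation, with a black bar at the median of the list and the adjusted p for the preset and for the estimated correlation beside it. 16 lists lie lower and 5 higher, and 0 of them pass with an estimated correlation.

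Markers of some other cell types were higher in PS-MP. Kupffer cell genes, of the resident macrophages of the liver, had 15 of 16 above zero (median 0.36, adjusted p = 0.000115; adjusted p = 0.553 with an estimated correlation). Marco, a scavenger receptor that binds particles and bacteria, averaged 2.81 ± 1.10 CPM in control and 13.3 ± 8.32 in PS-MP (SD, n = 3; log2 fold change 2.25, SE 0.52, adjusted p = 0.767), the complement gene C1qc had 0.45 and Adgre1, which encodes F4/80, 0.70. The call ended without control replicate 2 (adjusted p = 0.0546). Neutrophil genes had 5 of 7 above zero (median 1.10, adjusted p = 0.0107; adjusted p = 0.553 with an estimated correlation) at levels near 1 CPM. S100a9 (2.04, SE 0.52) and Csf3r (1.10, SE 0.33) rose when adjusted over the list alone, and S100a8 had 1.54. That call ended without control replicate 3 (adjusted p = 0.0861) and with library size alone (adjusted p = 0.0712). Erythroid genes had 5 of 7 above zero (median 0.62, adjusted p = 0.0213; adjusted p = 0.617 with an estimated correlation), led by the globin genes Hbb-bt (1.11), Hbb-bs (0.97) and Hba-a1 (0.62). This call ended without PS-MP replicate 3 (adjusted p = 0.179). The erythroid mean, 0.690, was 1.25 without control replicate 2. Yet that library had the lowest erythroid level, a mean log2 CPM of 4.21 against 4.40 and 4.46 in control replicates 1 and 3. The fit without it tested 18315 genes, so the members measured can differ, and 1.25 is not read as a larger rise. Skeletal muscle and mesothelium genes had 5 of 6 above zero (median 0.79, adjusted p = 0.0437; adjusted p = 0.662 with an estimated correlation), and the named members Msln (0.952 ± 0.512 CPM in control and 1.89 ± 0.273 in PS-MP, SD, n = 3), Upk1b (0.93) and Wt1 (0.78) mark mesothelium, the lining of the organ surface. Their call ended without control replicate 1 or 3 or PS-MP replicate 1 or 3 (adjusted p up to 0.408), with library size alone (adjusted p = 0.121) and without genes of wide spread (adjusted p = 0.0658). Their mean, 0.625, was 0.332 without control replicate 1 and 1.33 without control replicate 2.

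Proliferation genes were lower in PS-MP as a group. The cell cycle list had 24 of 30 genes below zero (median -0.27, adjusted p = 0.000319; adjusted p = 0.617 with an estimated correlation), with Cdc20 at 0.893 ± 0.113 CPM in control and 0.541 ± 0.0490 in PS-MP (SD, n = 3; log2 fold change -0.72), Aurkb at -0.75 and Mcm2 at -0.45. Its mean, -0.263, was -0.411 with the clock index, -0.0935 without control replicate 2, -0.174 without PS-MP replicate 1, -0.546 without PS-MP replicate 2 and -0.169 without PS-MP replicate 3. Interferon response genes were split, 15 above and 21 below zero (median -0.05, adjusted p = 0.0325; adjusted p = 0.845 with an estimated correlation), with Rsad2 at -0.60, Cmpk2 at -0.63 and Irf1 at -0.36. That call ended without control replicate 2 or 3 or PS-MP replicate 1 or 3 (adjusted p up to 0.831). The interferon mean, -0.0765, was -0.515 without PS-MP replicate 2, -0.120 without control replicate 1 and -0.389 with the clock index (adjusted p = 4.9e-05). It lay above zero without control replicate 2 (0.0172), without PS-MP replicate 1 (0.0267), without PS-MP replicate 3 (0.119) and with library size alone (0.150). With library size alone, where genes as a whole moved up, the list still passed as lower than the other genes (camera adjusted p = 0.0029).

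Clock genes varied widely among libraries of the same diet. Evening-phase genes were higher in PS-MP in 12 of 12 (median 0.93, adjusted p = 0.0456; adjusted p = 0.845 with an estimated correlation), with Per2 at 1.48, Hlf at 0.80 and Per3 at 1.94. Morning-phase genes had a median of -0.44 (adjusted p = 0.233). The mean log2 CPM of the evening list minus that of the morning list, a clock index, was -1.45, -1.90 and 1.03 in control and 1.83, 2.76 and -2.30 in PS-MP (two-sided exact permutation p = 0.5, n = 3 and 3). The evening call ended without control replicate 1 or 2 or PS-MP replicate 1 or 2 (adjusted p up to 0.480) and with library size alone (adjusted p = 0.418). The evening mean, 1.07, was 1.90 without control replicate 3 and 0.579 without PS-MP replicate 2.

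**Figure D4:**
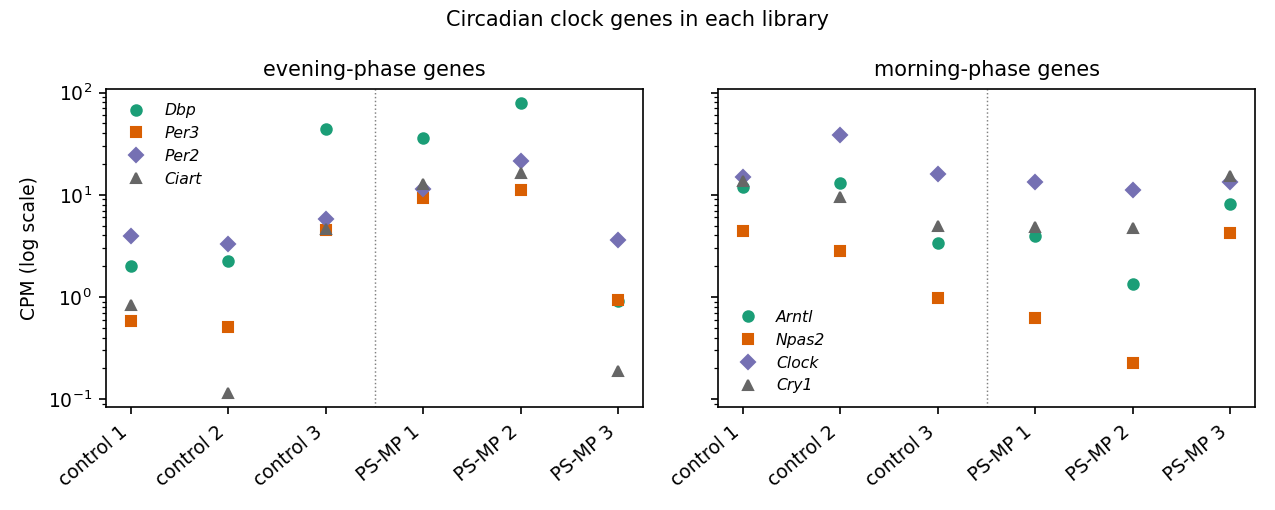
TMM-scaled CPM (log axis) of evening-phase clock genes (Dbp, Per3, Per2, Ciart) and morning-phase clock genes (Arntl, Npas2, Clock, Cry1), shown to illustrate the clock index, in each library. PS-MP replicates 1 and 2 lie high for evening genes and PS-MP replicate 3 lies low, with clock indices of 1.83, 2.76 and -2.30.

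The other 35 lists tested did not pass. Among metabolism lists, medians were -0.24 for cholesterol biosynthesis (adjusted p = 0.0554), -0.10 for lipoprotein and cholesterol export (0.223), 0.09 for gluconeogenesis (0.233), 0.16 for the urea cycle and amino acid catabolism (0.286), 0.02 for insulin and IGF signalling (0.675), 0.17 for iron and haem metabolism (0.613) and -0.02 for retinoid and vitamin D metabolism (0.613). Among cell types, they were 0.27 for sinusoidal endothelium (0.0554), 0.44 for dendritic cells (0.0844), 0.29 for T and NK cells (0.613), 0.18 for monocyte-derived macrophages (0.784), 0.03 for B and plasma cells (0.839), -0.08 for stellate cells (0.589), 0.07 for cholangiocytes (0.455), 0.13 for platelets (0.377), -0.03 for adipocytes (0.136) and 0.05 for hepatocyte identity (0.333). The adipocyte list, whose median is the value of Pck1, had the smallest p of fry (adjusted p = 0.159), with 4 of 7 genes below zero. Its library means did not overlap but almost touched, at 1.369 in control replicate 2 and 1.367 in PS-MP replicate 3. Those of sinusoidal endothelium did not overlap either, with PS-MP above (exact permutation p = 0.1 for both). Retn fell when adjusted over the adipocyte list alone. With its floor in place of its fitted value the adipocyte median does not move, since Retn stays the lowest of the list.

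The remaining stress and inflammation lists also did not pass. Medians were -0.14 for the heat shock response (adjusted p = 0.0860), -0.05 for the unfolded protein response (0.377), -0.11 for antioxidant enzymes and metallothioneins (0.499), 0.03 for p53 targets (0.996), 0.16 for senescence (0.606), 0.11 for glucocorticoid targets (0.589), 0.10 for immediate early genes (0.233) and -0.01 for lysosome and autophagy (0.377). They were 0.13 for acute phase proteins (0.589), 0.32 for cytokines and chemokines (0.233), 0.03 for MHC class II (0.985), 0.02 for complement and coagulation (0.976), 0.06 for fibrosis (0.308), 0.06 for oncofetal genes (0.739) and -0.11 for aryl hydrocarbon receptor targets (0.796). Median, mean and test differed in sign for 8 lists, namely antioxidant enzymes, stellate cells, retinoid metabolism, oncofetal, female-biased, aryl hydrocarbon receptor, B and plasma cell, and p53 lists. Too few genes were measured to test pancreatic acinar cells (1 gene, -0.10) and gut epithelium and gallbladder (3 genes, median 0.81). Of the 24 fixed genes 0 passed over all genes with edgeR (3 at an unadjusted p under 0.05), 0 with limma-voom and 1, Hmox1, with DESeq2. Mt1 varied widely between libraries, at 38.5 ± 26.7 CPM in control and 461 ± 540 in PS-MP (SD, n = 3, log2 fold change 3.58). Ddit3 had 0.87 (interval -0.34 to 2.09), Cdkn1a -1.80 (-3.91 to 0.30), Lcn2 0.96 (-0.47 to 2.39), Saa1 0.08 (-0.50 to 0.65), Tnf 0.40 (-0.88 to 1.69), Col1a1 -0.04 (-0.63 to 0.55) and Alb 0.15 (-0.34 to 0.64).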

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

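The fits with the clock index, without ribosomal RNA genes and without genes of wide spread were chosen only after the data were seen. The count of 2 genes past the threshold stayed at 2, with both genes shared, under 3 other scalings, no filter (30222 genes), the 1 CPM filter (12488 genes), robust dispersions, both other thresholds, and without mitochondrially encoded genes, ribosomal RNA genes or the 425 genes of wide spread. It was 187 with DESeq2 (2 shared), 1 with limma-voom, 0 with the replicate number as a block and 1 with the clock index, and 0 to 4 with 1 library left out; fewer samples enter the last, and otherwise the cause was not tested. After removing diet, libraries of the same number correlated at 0.108, 0.139 and -0.128 and others at -0.185 to 0.0970; replicates 1 and 2 correlated best with their own number and replicate 3 did not, and the numbers were not taken to pair the libraries. Dennd5b had adjusted p from 0.0150 to 0.302 across its alternatives other than DESeq2, with 0.141 for the block and 0.299 with the clock index. Gm5526 had adjusted p from 0.00213 to 0.141 across its alternatives other than DESeq2, the highest with the block. The 21 lists became 0 with an estimated correlation and 0 with fry, and the cause was not tested for either. A higher correlation between genes is not the whole of the former. The adipocyte list had an estimated correlation of -0.0313, below the preset 0.01, yet its unadjusted camera p rose from 0.0632 to 0.128. Lists past the threshold were 24 with ranks, 21 with DESeq2-type factors (all shared), 20 with library size alone (2 higher and 18 lower, 17 shared) and 17 with the 1 CPM filter. With the block they were 20 (3 higher and 17 lower, 19 shared), with the clock index 21 (18 shared), and with 1 library left out 15 to 24. The mean of the interferon response list ranged from -0.515 to 0.119 with 1 library left out, where 0.119 came without PS-MP replicate 3, and the cause was not tested. With the block the mean of that list was -0.184 and the mean of fatty acid synthesis was -0.234, and both lists kept their calls. The mean of the evening-phase list was -0.145 with the clock index, which is built from that list. Metabolic genes inside 2-fold numbered 183 to 198 across alternatives and 159 to 179 with 1 library left out. The ratio of distances was 1.05 to 1.17 across alternatives and 1.03 to 1.13 with 1 library left out. Of 97 named genes, 82 kept one sign in every setting. Low depth per gene limits Gm5526 and Retn, whose lower group held 3 and 0 counts.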

Other observations

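The tests of neighbouring genes, of clock phase as the whole cause, of ribosomal RNA within a diet, of the hepatocyte share and of the splits for fatty acid synthesis were chosen only after the result was seen, as were the genes singled out here.

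Several genes varied widely among libraries of one diet. Mup7, which encodes a major urinary protein secreted by the male liver, stood at 85.7 and 233 CPM in PS-MP replicates 1 and 2 but at 3803 CPM in PS-MP replicate 3, and between 2270 and 6651 CPM in control. Mup1 had 98.5, 266 and 2124 CPM in the same PS-MP replicates. The metallothionein gene Mt1 had 1067, 287 and 28.9 CPM there and 38.5, 11.8 and 65.3 CPM in control. Elovl3, a fatty acid elongase, had 83.4, 63.5 and 585 CPM in PS-MP and 583, 409 and 224 CPM in control. The immunoglobulin light chain gene Igkc was at 0.138, 124 and 0.113 CPM in control and 76.4, 127 and 37.0 CPM in PS-MP.

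The number of genes called was 2 for the diets and at most 1 in the other splits of the 6 libraries; 1 of 10 splits gave as many. For lists it was 21 for the diets and at most 23 in the others, and 3 of 10 splits gave as many. Metabolic genes inside 2-fold numbered 191 for the diets and up to 208 in the others, and 3 of 10 splits gave as few. The 10 splits are too few for a share under 0.05. DESeq2 called 187 genes for the diets and 31 to 268 in the other splits. Genes at an unadjusted p under 0.05 with edgeR numbered 950 for the diets and 315 to 1859 in the others, 4 of which had more.

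Dennd5b was low (66, 125 and 96 counts) and Gm5526 near the floor in the control libraries, and both were high in every PS-MP library. The counted neighbours of Dennd5b were too low to be the source of its gain of 77.8 CPM, since the highest in control, Etfbkmt, had 11.1 CPM. The largest fall among them, 5.10% of that gain, could therefore not be large and is no further test. Reads assigned to no gene are not seen in these counts. The neighbour Amn1 was higher too, at 5.94 CPM in control and 12.2 CPM in PS-MP (log2 fold change 1.04, edgeR adjusted p = 0.767). Gene counts that switch on and off between libraries whatever the diet remain a candidate explanation, by a test written before its result. In 4 of the 10 splits, that by diet included, some gene had its low and high libraries at least 4.29 log2 units apart, the gap of Gm5526, and 16 genes such as Prdm2 were lost in one library alone. Gaps over 2-fold were more numerous by diet (69 genes) than in any other split (at most 38), but gaps over 4-fold were not (5 genes, and up to 5 in the others), and an effect of diet on the pair stays open.

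Clock gene levels were spread among libraries of one diet, where the clock index ranged over 2.93 within control and 5.06 within PS-MP. The evening and morning lists moved in opposite directions in 5 of the 6 pairs of libraries of one diet. The labels give no time of collection.

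The fatty acid synthesis list was lower in PS-MP, with a mean of -0.370; in size, 3 of the 10 splits reached this, the highest other 0.455, and the splits are too few for a share under 0.05. A smaller share of hepatocytes is argued against, since the hepatocyte identity list had a mean of 0.122 and stayed between 0.0122 and 0.292 with 1 library left out, where fatty acid synthesis lay between -0.536 and -0.149. Ribosomal RNA carried into the libraries is argued against too, since in 0 of the 6 pairs of libraries of one diet did more Rn18s-rs5 go with a higher list mean. In each pair more Rn18s-rs5 went with a lower list mean, the opposite of the difference between the diets. The pairs come from 3 libraries per diet and are not independent. With the clock index as a covariate the list mean was -0.329 and the list still passed with the preset correlation (adjusted p = 0.00284), which argues against clock phase as the whole cause only as far as that test goes, since neither fit passes with an estimated correlation (adjusted p = 0.724 with the clock index and 0.553 without it). Whether clock phase caused 50% of the change was left undecided by a test written before its result. The mean with the index, -0.329, lay further below zero than 50% of -0.370, but not by the margin that the test asked for. That test used the SD of the leave-one-out means, 0.150. Those means share libraries, so their SD does not measure the sampling error of the list mean. An effect of PS-MP stays open.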
